A study of Mus musculus with 10 samples.

How the data were processed

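RNA with poly(A) tails from peritoneal lavage cells of 10 samples, 5 labelled AX and 5 labelled NC, was made into libraries with the VAHTS Universal V6 kit after extraction with MJzol, per the labels' protocols. Reads were aligned by the authors with HISAT2 2.0.4 to mouse build mm10, per the submitters' processing notes. The counting tool, the annotation release and the use of strand are not given in the sources used here. The deposited table holds 34745 genes with a raw count and an FPKM value for each sample. The counts deposited by the authors are whole numbers that were not normalised. The FPKM values deposited by the authors equal the count divided by a gene length and by the total of the count column, with a largest relative gap of 1.69e-05 over 7639 genes. Beyond the counts they therefore carry only a gene length, which was taken from them to compare the lengths of lost genes. Otherwise they were used only in an alternative test. Coordinates are those of the file, 1-based on mm10; 34344 gene identifiers were found in GENCODE M21 and 27772 had the same span there. Every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom from 41.8 to 327), so all 10 were kept as separate samples. Nothing in the labels says that each sample came from a separate animal, and if they did not, p-values measure only the spread between these samples, which may be technical.

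Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as argument, library sizes were scaled by TMM, and AX was compared with NC by the two-sided quasi-likelihood F test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were derived from the fold change and its F statistic, and 95% intervals from the moderated degrees of freedom. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. A list level is the mean log2 CPM of its tested members in a library, and list levels and single genes were compared by exact two-sided permutation over all arrangements of 5 and 5, which cannot give a p below 0.00794. The 43 lists, 23 of functions and 20 of cell types or RNA quality, held 843 symbols, of which 16 had no match in the table, most of them newer names of genes listed under older ones; 3 lists, of plasmacytoid dendritic cells, of eosinophils and basophils and of platelets, had fewer than 5 tested members and were not tested.

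The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule Il10, Ldha, Ldhb, Slc16a1, Slc16a3, Tbk1, Ikbke, Tnf, Il6 and Il1b are always reported. In each direction up to 10 genes with the largest change, an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap of the groups were to be named, leaving out predicted genes, Rik clones and receptor segments. Since none passed, the 10 genes with the smallest p in each direction are given as values, with the same exclusions and the same minimum level. In each list described, up to 4 members with the smallest p are eligible. S100a8, S100a9, Ep300, Isg15, Adgre1 and the genes of the closing section other than these were chosen after their values were seen.

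Alternatives were DESeq2 1.42.0, limma-voom with and without library quality weights, other scalings, no or a stricter filter (50 counts in 5 libraries), limma on log2(FPKM + 1) for genes at 1 or more in 5 libraries, the neutrophil or macrophage list as covariate, and leaving out each library in turn. Alternatives written for a table without counts (quantile normalisation and other pseudocounts) did not apply. A gene counted as lost in a library when its CPM lay at least 8-fold below the larger of the group medians, with a pseudocount of 0.5 and a median of at least 20 CPM. Other splits of the 10 libraries into 5 and 5 were tested for 100 of 126 possible splits. Gene-level and list-level steps were tested on simulated data. For this comparison, with 12056 genes tested and 200 changed, 4 of 100 genes changed 2-fold and 73 of 100 changed 4-fold were recovered, with 4 false calls. All 3 lists shifted by 0.5 log2 were recovered, and 0 of 37 other lists were called. The simulated genes varied independently of each other, so this could not test false calls from correlated members. Other splits of the real libraries called a median of 10 lists. The step for lost genes recovered 199 of 200 planted 20-fold drops among 5908 eligible genes. Each drop was planted in a single library of a steady gene, so losses in several libraries were not tested. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 was used for the permutation tests of lost genes and the plots. Intervals and counts cover these libraries only, since no molecular identifiers are described.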

Results

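Messenger RNA was sequenced from peritoneal lavage cells, the mixed leukocytes and shed lining cells washed out of the abdominal cavity, of mice with polymicrobial sepsis caused by cecal ligation and puncture. The labels divide the 10 libraries into 5 named AX and 5 named NC. Because the series compares amlexanox with vehicle, AX was read as amlexanox and NC as vehicle, although the labels do not spell out either abbreviation. Amlexanox is a small anti-inflammatory molecule known to inhibit the kinases TBK1 and IKKε and cyclic nucleotide phosphodiesterases. Total counts per library ran from 10221170 in NC 1 to 13806885 in NC 2, and an exact two-sided permutation test of the totals between the groups gave p = 0.587 (n = 5 each). Between 11865 and 12851 genes per library had at least 10 counts. Levels are normalised read counts scaled to library size (CPM), means are given with the SD over 5 libraries, and fold changes are AX against NC.

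The series title places IL-10 production at the centre of the study, so the first comparison asked whether Il10 mRNA differed between the groups. Il10, which encodes the anti-inflammatory cytokine IL-10, was abundant in all 10 libraries, at 768 ± 378 CPM in AX and 998 ± 494 CPM in NC (n = 5 each). The difference was smaller than the spread between libraries: the log2 fold change was -0.38 with a standard error of 0.42, and its 95% interval, from -1.31 to 0.55, covers folds from 0.404 to 1.47. An exact two-sided permutation test of the group means gave p = 0.389. The gene (ENSMUSG00000016529) lies on chromosome 1 from 131019845 to 131024974 of mm10. The NC mean was raised by a single library, NC 3, at 1878 CPM; the other 4 NC libraries lay between 728.6 and 828.3 CPM. AX values ranged from 242.9 CPM in AX 10 to 1111 CPM in AX 8. Without NC 3 the log2 fold change was -0.02.

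No gene of lactate production or transport passed the threshold. Ldha, the main lactate dehydrogenase subunit of glycolytic cells, stood at 1842 ± 332 CPM in AX and 2104 ± 393 CPM in NC, a log2 fold change of -0.19 with a 95% interval from -0.64 to 0.25. Slc16a3, which encodes the lactate exporter MCT4, stood at 481.8 ± 56.8 against 560.99 ± 153 CPM, with a log2 fold change of -0.22 ± 0.21 (SE). Slc16a1, which encodes the lactate transporter MCT1, stood at 392 ± 164 against 371 ± 80.2 CPM; its log2 fold change of 0.08 ± 0.27 (SE) became -0.21 without AX 6, the library with the highest value, 674.6 CPM, and -0.01 without NC 5. Ldhb, the other lactate dehydrogenase subunit, was near the detection limit, at 0.756 ± 0.539 against 1.19 ± 0.343 CPM, a fold of 0.641 with a 95% interval from 0.307 to 1.34. In the fixed list of glycolysis and lactate genes, 12 of 27 tested members had a higher and 15 a lower fitted value in AX. None of the 27 passed, whether adjusted over all genes or adjusted over the list alone, and the list itself gave adjusted p = 0.835 with camera. Hk1, a hexokinase, showed a log2 fold change of -0.98 ± 0.60 (SE), with 126 CPM in NC 3 and 9.08 to 33.5 CPM in the other libraries.

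Histone lactylation is named in the series title, and a list of 22 tested enzymes and readers of histone acylation was therefore examined. Their fold changes were close to 0: 11 members were higher and 11 lower in AX, with a median log2 fold change of 0.00 and an adjusted camera p of 0.663. Ep300, an acetyltransferase, stood at 120 ± 49.6 CPM in AX and 110 ± 27.0 CPM in NC. Hdac2 and Hdac3, class I deacetylases, had log2 fold changes of -0.15 ± 0.17 and -0.10 ± 0.16 (SE). No member passed over all genes, and 0 passed adjusted over the list alone.

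The mRNAs of the kinases that amlexanox inhibits and of the inflammatory cytokines likewise did not pass the threshold. Kinase activity, histone lactylation, lactate and IL-10 protein were not measured in these data. Tbk1 stood at 104 ± 12.04 CPM in AX and 114 ± 27.2 CPM in NC, a log2 fold change of -0.13 ± 0.19 (SE). Ikbke, which encodes IKKε, stood at 702 ± 406 against 795 ± 254 CPM; AX 6 held only 48.4 CPM where the other 4 AX libraries held 585 to 1049, and without AX 6 the log2 fold change turned from -0.18 to 0.12. Tnf, a major early cytokine of sepsis, stood at 506 ± 106 against 549 ± 118 CPM, and Il1b at 1910 ± 572 against 1955 ± 616 CPM. Il1b had a log2 fold change of -0.03 ± 0.30 (SE), which changed sign without NC 3, NC 4, AX 7 or AX 10 (0.09, 0.06, 0.02 and 0.12). Il6 was much more variable, at 80.4 ± 123 CPM in AX, where AX 6 alone reached 299.1 CPM, and 42.6 ± 33.0 CPM in NC, where NC 1 reached 100.3 CPM. Its log2 fold change of 0.92 ± 0.85 (SE) became -0.72 without AX 6.

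**Figure D1:**
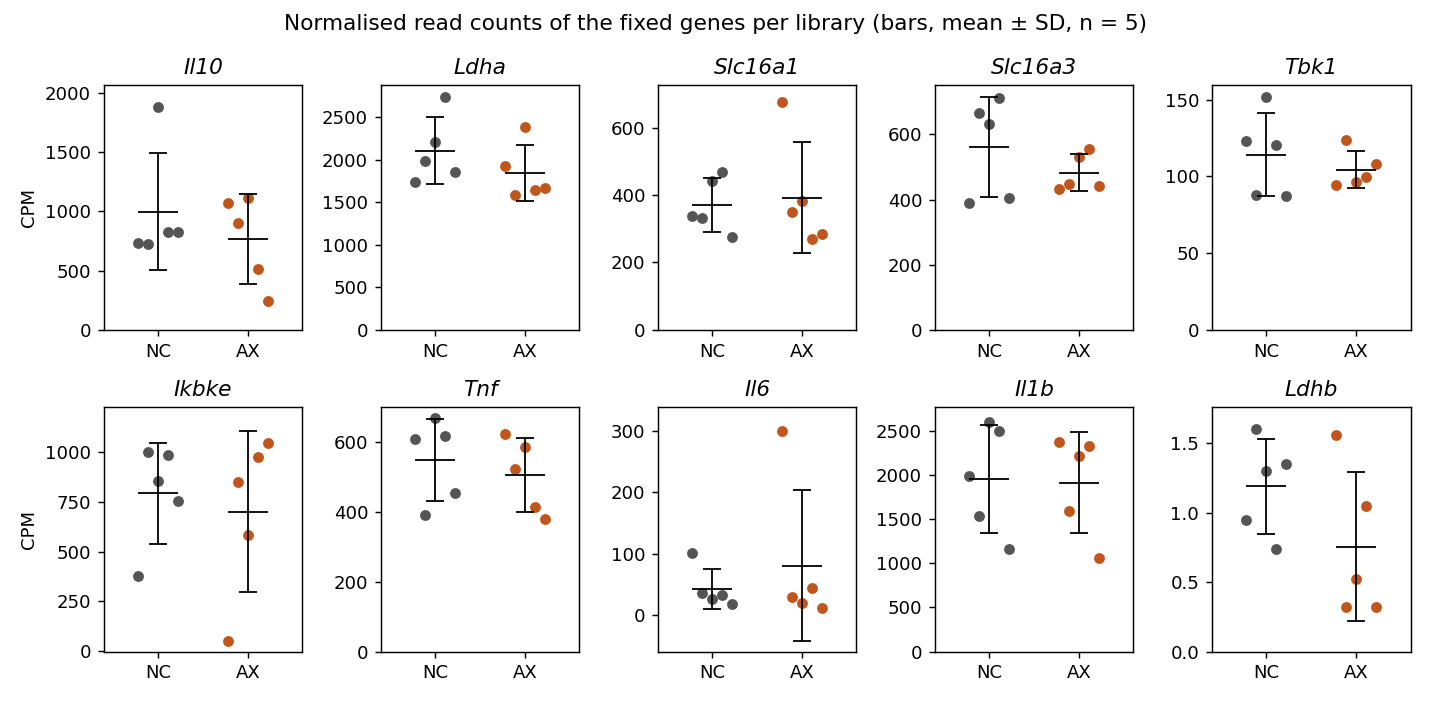
Normalised read counts (CPM) of the 10 genes fixed beforehand, for the 5 NC libraries (grey) and the 5 AX libraries (orange); each point is a library, and the horizontal bar and whiskers are the mean and SD. The groups overlap for all 10 genes, NC 3 lies above the other NC libraries for Il10 at 1878 CPM, and AX 6 lies apart for Ikbke (48.4 CPM) and Il6 (299.1 CPM).

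Across the transcriptome no gene passed the adjusted threshold between AX and NC. Of 12264 genes tested with the quasi-likelihood test of edgeR, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 1.0. At an unadjusted p under 0.05 there were 113 genes, 50 with a higher and 63 with a lower value in AX, which is 0.921% of the genes tested where 5% are expected by chance. DESeq2 also called 0 genes with 193 at an unadjusted p under 0.05, limma-voom called 0 with 132, and limma-voom with library quality weights called 0 with 380. The groups did not overlap for 17 genes, or 0.139%, while chance gives 0.794%. Typical precision was limited: the median standard error of a log2 fold change was 0.317 and the common biological coefficient of variation was 0.476. On simulated counts for this comparison, with 12056 genes tested and 200 changed, the test recovered 73 of 100 genes changed 4-fold and 4 of 100 changed 2-fold. Differences of 2-fold could therefore have been missed. Among unchanged simulated genes 4.33% had an unadjusted p under 0.05, against 0.921% of the genes tested here. The adjusted threshold is also stricter when fewer genes change. Recovery of 4-fold changes may thus be lower in these data than in the simulation.

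The genes with the smallest unadjusted p are given as values, since none passed the adjusted threshold (adjusted p = 1.0 with edgeR for each). Os9, an endoplasmic reticulum lectin of protein quality control, stood at 71.9 ± 10.04 CPM in AX and 118 ± 20.99 CPM in NC, with all 5 AX values below all 5 NC values. Prpsap1, a regulatory subunit of phosphoribosyl pyrophosphate synthesis, stood at 20.97 ± 1.18 against 28.5 ± 1.07 CPM, and Acp5, the tartrate-resistant acid phosphatase of macrophages and osteoclasts, at 120 ± 15.4 against 165 ± 20.8 CPM. Etfb, which passes electrons from fatty acid oxidation to the respiratory chain, stood at 44.3 ± 3.45 against 59.8 ± 7.96 CPM, and the mitochondrial iron-sulfur protein gene Cisd3 at 10.7 ± 1.92 against 16.8 ± 3.58 CPM. Pacsin2, AI413582 and Edc4 had log2 fold changes of -0.79 ± 0.24, -0.61 ± 0.19 and -1.13 ± 0.36 (SE). Among those with higher values in AX, the p53 target Trp53inp1 stood at 133 ± 47.6 against 79.2 ± 3.15 CPM, with 4 of 5 AX libraries above every NC library. Adat3 stood at 9.25 ± 1.69 against 4.28 ± 1.51 CPM and Plekhg3 at 32.5 ± 4.703 against 21.3 ± 4.84 CPM, both without overlap of the groups. Serpinh1, a collagen chaperone, stood at 84.5 ± 69.2 against 34.0 ± 9.19 CPM, with 202.5 CPM in AX 6. Prmt1, Mynn, Pcbp4 and Gtf2ird2 had log2 fold changes of 1.93 ± 0.62, 1.51 ± 0.48, 1.52 ± 0.56 and 0.99 ± 0.36 (SE).

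Several of the largest fitted folds rested on a few libraries. Rasa3, a GTPase-activating protein for Ras, showed 51.4, 63.7 and 59.9 CPM in AX 7, AX 9 and AX 10 but 0.731 to 8.07 CPM in all other libraries. By the rule for genes nearly absent from some libraries, Rasa3 was lost in 6 of them (NC 1, NC 3, NC 4, NC 5, AX 6 and AX 8), so its fold belongs to that pattern. Srcap, a chromatin remodeller, showed 39.4 and 49.3 CPM in AX 6 and AX 8 and 0.809 to 4.92 CPM elsewhere. Its overlapping gene on the same strand, Gm42715, was lost in AX 6 by that rule but not in AX 8. Gm42715, chosen after its values were seen, had 2.6 CPM in AX 6 and a median of 54.5 CPM in the other libraries. Clock, a circadian transcription factor, showed 45.8 and 34.1 CPM in NC 1 and NC 2 and 2.42 to 4.01 CPM elsewhere. Pcmtd2 reached 32.5 CPM in NC 5, 11.2 CPM in NC 2 and 8.92 CPM in NC 4, with 0.607 to 1.38 CPM in the other libraries. Of the 10 fixed genes and these 20 with the smallest p, 13 overlap another annotated gene, 7 of them on the same strand, among them Adat3 (with Scamp4), Prmt1, Srcap, Edc4, Etfb and Clock, and reads in the overlaps cannot be assigned with certainty.

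Gene lists were compared to ask whether related genes moved together where single genes did not. Nuclear-encoded genes of oxidative phosphorylation lay slightly lower in AX: 35 of 39 tested members had a lower fitted value and 4 a higher one, with a median log2 fold change of -0.18. Examples are Ndufb8 of complex I at 50.7 ± 7.87 against 68.8 ± 11.3 CPM, the cytochrome oxidase subunit gene Cox4i1 at 237 ± 27.3 against 325 ± 85.1 CPM, and the ATP synthase subunit gene Atp5f1 at 191 ± 58.3 against 272 ± 31.2 CPM. This list passed camera with a preset correlation of 0.01 (adjusted p = 4.32e-07) but gave adjusted p = 0.544 with an estimated correlation, and an exact permutation test of the mean list level gave p = 0.0714. Genes of pyruvate entry and the citric acid cycle had 21 of 28 members lower in AX (median log2 fold change -0.07, adjusted p = 0.0205, and adjusted p = 0.835 with an estimated correlation), with Idh2 at 15.8 ± 2.72 against 21.2 ± 3.25 CPM. That call ended on leaving out NC 1, NC 4, AX 7, AX 8, AX 9 or AX 10 in turn (adjusted p = 0.116, 0.0699, 0.0598, 0.0564, 0.0718 and 0.172). Mitochondrially encoded genes, in contrast, had 12 of 13 members higher in AX (median 0.45, adjusted p = 0.00867, and adjusted p = 0.835 with an estimated correlation), with mt-Co1 at 49359 ± 26357 against 33234 ± 13941 CPM. The exception was mt-Nd6, which is transcribed from the other DNA strand, at 36.2 ± 17.3 against 139 ± 174 CPM. The mitochondrial share of all counts was 13.1 ± 6.09% in AX and 9.72 ± 4.44% in NC (exact permutation p = 0.333, n = 5 each), and the call ended without NC 1, NC 2, AX 6, AX 8 or AX 10 (adjusted p = 0.116, 0.601, 0.0693, 0.242 and 0.332). That call also ended with the neutrophil list as covariate and without AX 6 and NC 1 together.

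Cell cycle genes lay lower in AX, with 23 of 27 members lower and a median log2 fold change of -0.42 (adjusted p = 1.14e-05, and adjusted p = 0.835 with an estimated correlation). Their levels were low, as for the cyclin gene Ccnb2 at 4.05 ± 1.90 against 6.70 ± 1.30 CPM and the mitotic kinase gene Plk1 at 2.74 ± 1.34 against 4.72 ± 1.42 CPM. Without AX 10 the list gave adjusted p = 0.0796. In none of these 4 lists did a member pass over all genes, and 0 members passed adjusted over the list alone.

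Markers of other cell types were compared to see whether the cell mixture differed. All 14 tested mesothelial markers, genes of the cells lining the peritoneum, were higher in AX with a median log2 fold change of 1.02 (adjusted p = 0.0164, and adjusted p = 0.835 with an estimated correlation), and all 15 stromal markers were higher with a median of 0.55 (adjusted p = 0.00021, and adjusted p = 0.835 with an estimated correlation). Both calls ended without AX 6. Msln, the mesothelial surface protein mesothelin, stood at 821 CPM in AX 6, 206.2 CPM in NC 1 and 29.9 to 116.5 CPM in the other libraries, and without AX 6 the mesothelial list gave adjusted p = 0.85 in the opposite direction and the stromal list adjusted p = 0.329. With NC 1 left out as well as AX 6, the stromal list passed again in the same direction (adjusted p = 0.000375) and the mesothelial list did not (0.0883). The stromal list did not pass with the mesothelial list as covariate. The mesothelial call also ended without NC 2, NC 4 or NC 5 (adjusted p = 0.335, 0.112 and 0.0751), and with no filter on low counts. Markers of large peritoneal macrophages, the resident phagocytes of the cavity, were higher for 16 of 19 members (median 0.51, adjusted p = 0.0085, and adjusted p = 0.835 with an estimated correlation). Prg4 stood at 45.3 ± 44.7 against 22.7 ± 13.6 CPM and Fcna at 13.6 ± 13.4 against 5.67 ± 4.30 CPM, while Adgre1, which encodes F4/80, stood at 68.1 ± 42.2 against 74.0 ± 49.0 CPM. The macrophage call ended without AX 9 or NC 3 (adjusted p = 0.24 and 0.0625). Gut epithelial and other tissue markers were lower in AX for 10 of 11 members (median -0.94, adjusted p = 0.0519), and passed without NC 2, NC 3, NC 5 or AX 6 (adjusted p = 0.00225, 0.013, 0.0284 and 0.000143), with adjusted p = 0.835 with an estimated correlation and all libraries. No member of these 4 lists passed over all genes, and 0 passed adjusted over the list alone.

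Apart from large peritoneal macrophages, lists of the main leukocyte types did not pass with all 10 libraries. Of 21 tested neutrophil markers, 16 had a lower value in AX (median log2 fold change -0.15, adjusted p = 0.31; without NC 1, adjusted p = 0.00812). The neutrophil alarmin genes S100a8 and S100a9 stood at 2124 ± 584 against 2132 ± 765 CPM and at 4767 ± 1816 against 4050 ± 1004 CPM. Lists of monocytes (adjusted p = 0.791), conventional dendritic cells (0.767), B cells (0.687) and T cells (0.602) did not pass. The B cell list passed as lower in AX without NC 3 (adjusted p = 0.0371) and the T cell list as higher without NC 5 (0.00476). These calls used the preset correlation; with an estimated correlation and all libraries, the neutrophil, B cell and T cell lists gave adjusted p = 0.88, 0.951 and 0.921.

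Inflammatory function lists did not pass with all 10 libraries, but several did when 1 library was left out. Among IL-10 and its targets, 11 of 17 members were lower in AX (median log2 fold change -0.04, adjusted p = 0.0652); Socs3, a feedback inhibitor induced by IL-10, stood at 1227 ± 263 against 1517 ± 355 CPM, and Bcl3 at 216 ± 48.9 against 285 ± 46.3 CPM. The IL-10 list passed as lower without NC 5 or AX 7 (adjusted p = 0.00351 and 0.0173). For the type I interferon response, which TBK1 and IKKε help to start, 27 of 31 members were higher (median 0.19, adjusted p = 0.111), with Isg15 at 123 ± 84.7 against 99.5 ± 45.8 CPM, and the list passed as higher without NC 4, NC 5, AX 7 or AX 9 (adjusted p = 0.0038, 0.0424, 0.00172 and 0.0081). Targets of NF-κB had 16 of 24 members lower (median -0.08, adjusted p = 0.0684) and passed without NC 2, NC 4, NC 5, AX 6 or AX 8 (adjusted p = 0.0176, 0.0303, 0.00954, 0.00119 and 0.0311). Targets of cyclic AMP signalling had 16 of 21 higher (median 0.19, adjusted p = 0.122) and passed without NC 3 (adjusted p = 0.00276). All these calls used the preset correlation; with an estimated correlation and all libraries, the interferon list gave adjusted p = 0.88, and the IL-10, NF-κB and cyclic AMP lists gave 0.835 each. Inflammatory cytokines (adjusted p = 0.977), chemokines (0.524) and TBK1 and IKKε signalling (0.524) did not pass with all libraries or without any 1 of them. Efferocytosis and scavenger receptor genes had the only list level with an exact permutation p under 0.05 (0.00794, the smallest the design allows, and 0.317 after adjustment over the lists), at a mean of 4.61 ± 0.12 against 4.47 ± 0.07 log2 CPM. In total 7 of 40 lists passed camera with the preset correlation, 0 passed with an estimated correlation, and 0 passed with fry, whose smallest adjusted p was 0.995. The 33 other lists had adjusted p from 0.0519 to 0.977, and no member of any list passed, adjusted over all genes or adjusted over the list alone. For 11 lists, among them chemokines, inflammatory cytokines, TBK1 and IKKε signalling and the unfolded protein response, the median, the mean and the test differed in sign.

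**Figure D2:**
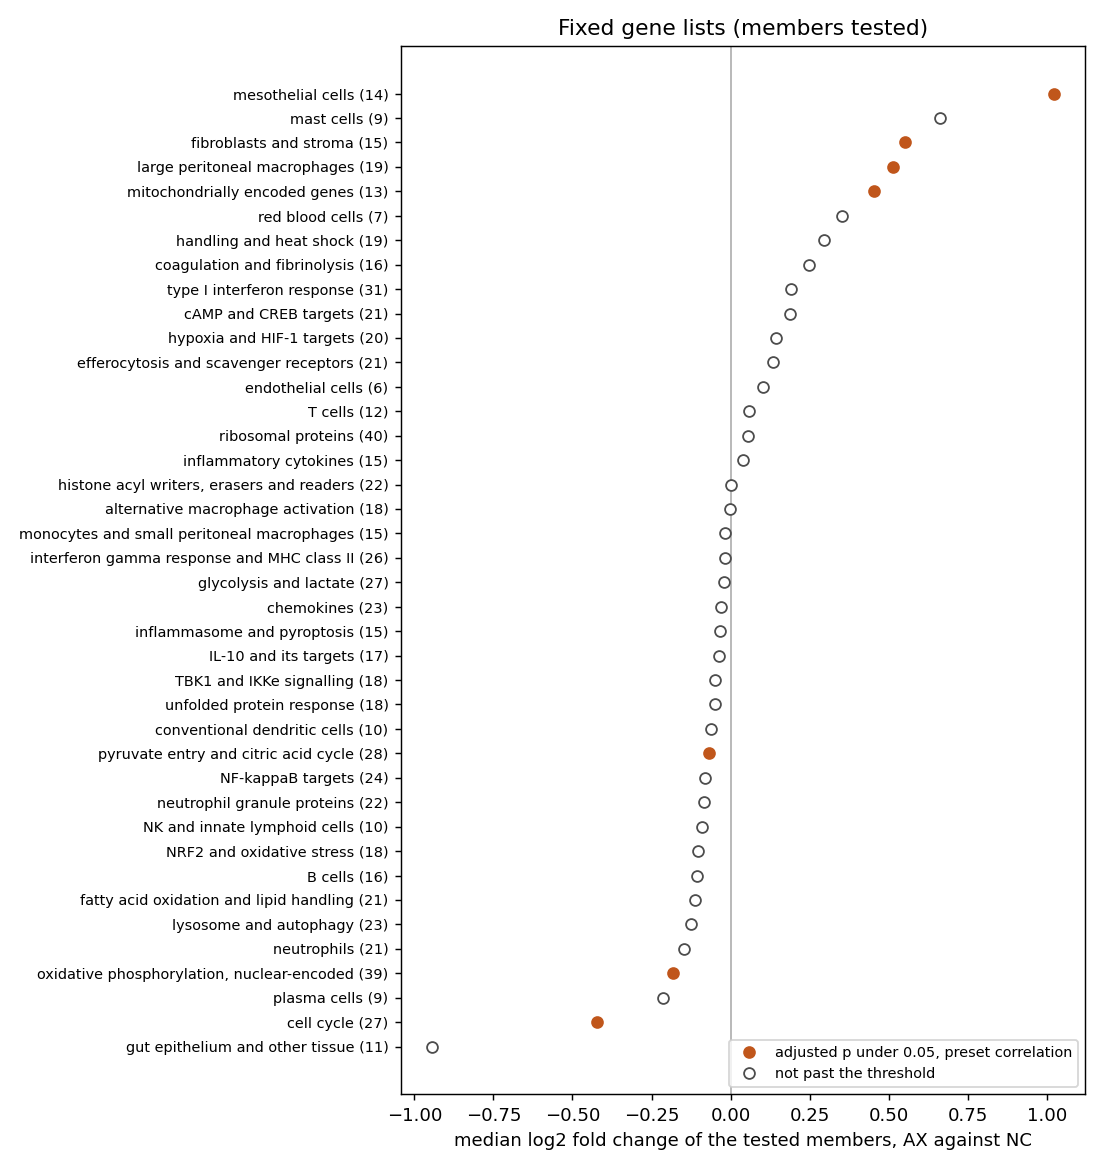
Median log2 fold change, AX against NC (horizontal axis), of the tested members of each of the 40 fixed gene lists, with the number of members tested in parentheses; filled points are the 7 lists past an adjusted p of 0.05 in camera with a preset correlation, and open points are the other 33. Medians run from -0.94 for gut epithelium and other tissue to 1.02 for mesothelial cells, and none of the 7 calls held with an estimated correlation.

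The libraries did not divide by group. The first principal component, with 42.8% of the variance, set AX 6 (-110.5) and NC 1 (-74.9) apart from the other 8 libraries (2.65 to 61.9), and a comparison of the groups along it gave an exact permutation p of 0.81. For each of the 10 libraries the most similar other library, by Spearman correlation across genes, belonged to the other group. The median correlation was 0.934 over the 20 pairs within a group and 0.939 over the 25 pairs between groups, values that describe these libraries because genes are not independent replicates.

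**Figure D3:**
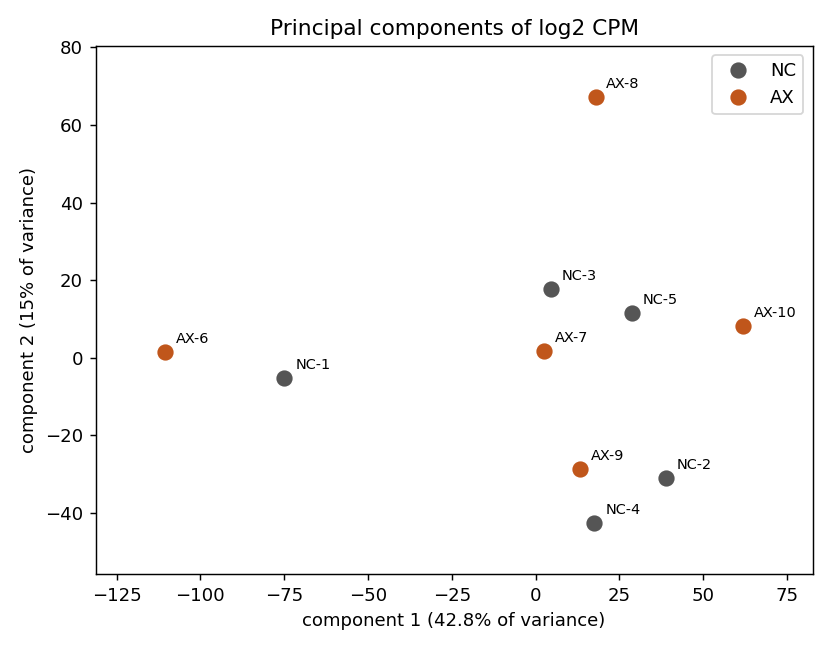
Scores of the 10 libraries on the first 2 principal components of log2 CPM, with the percent of variance on each axis; NC libraries are grey and AX libraries orange. AX 6 and NC 1 lie together at the left, at -110.5 and -74.9 on the first component, and the other libraries of both groups are mixed.

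Some genes abundant in part of the libraries were nearly absent from 1 or more of the others. Under a rule of at least 8-fold below the larger group median, 127 genes were lost in 1 library, 50 in 2 and 37 in 3 or more. Libraries lost from 19 genes in AX 7 to 65 in AX 8, with means of 40.6 ± 19.0 in AX and 34.8 ± 13.9 in NC (exact permutation p = 0.619, n = 5 each). Ptprc, which encodes the leukocyte surface protein CD45 and overlaps another annotated gene on the same strand, stood at 22.4 CPM in AX 8 and at 355 CPM or more in the other libraries. Sirpa, a myeloid inhibitory receptor, stood at 28.2 CPM in NC 2, 15.5 CPM in AX 7 and 8.14 CPM in AX 8, and at 133.8 to 931.8 CPM elsewhere. Tmem127 had 0.867 CPM in AX 6 and 114.9 CPM or more elsewhere. With the 214 genes marked by this rule left out, edgeR still called 0 genes, with 111 at an unadjusted p under 0.05. Genes low in most libraries of both groups, such as Srcap, are not marked by the rule and stayed in.

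**Figure D4:**
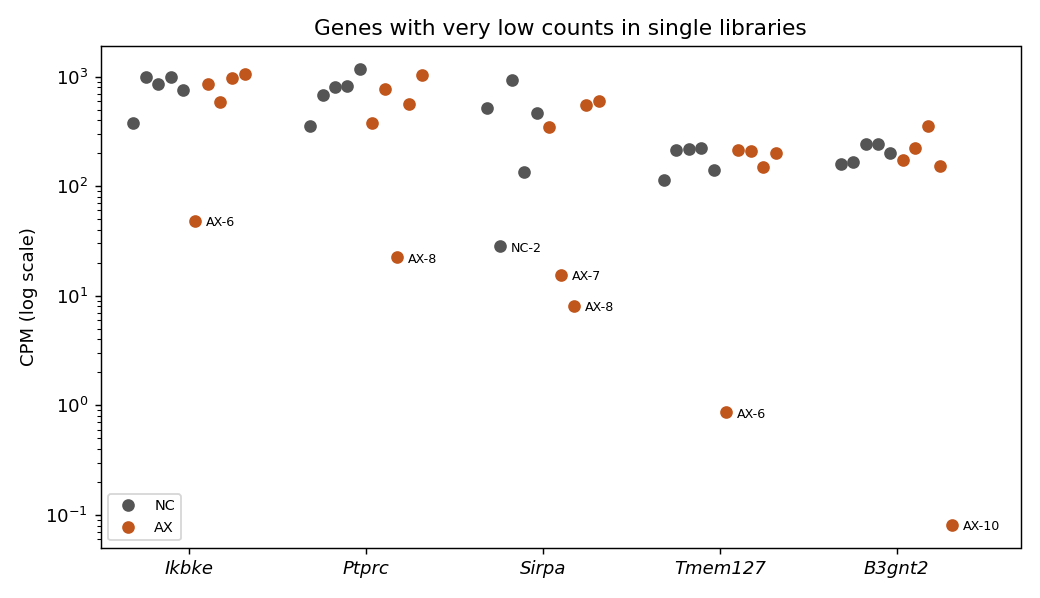
Normalised read counts (CPM, log scale) of 5 genes with very low values in 1 to 3 libraries, chosen after their values were seen; each point is a library, grey for NC and orange for AX, and the lowest libraries are named. B3gnt2 has 0.0811 CPM in AX 10, Tmem127 0.867 CPM in AX 6, and Sirpa is low in NC 2, AX 7 and AX 8. Of these genes, B3gnt2 and Ptprc overlap other annotated genes on the same strand.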

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

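Chosen after the results were seen were the tests of abundance, of genes without an overlapping gene, of length and of the group among lost genes, all 3 tests of the pair of libraries that stand apart, and both counts of changed genes over other splits. A single library lay far from the other 4 of its group in 7 of 146 groups tested, where chance at 1 in 20 gives 7.30. The T cell list reached 1.98 mean log2 CPM in AX 8, against 1.03 to 1.16 in the other AX libraries, and 2.14 in NC 5, against 0.83 to 1.16 in the other NC libraries. The conventional dendritic cell list was low in NC 3, at 2.94 against 3.61 to 3.87. Il10 was high in NC 3, at 10.88 on the log2(CPM + 1) scale against 9.51 to 9.70. Ikbke was low in AX 6, at 5.63 against 9.20 to 10.04, and in NC 1, at 8.56 against 9.56 to 9.97. Etfb was high in NC 5, at 6.22 against 5.78 to 5.89.

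Genes abundant in some libraries were almost absent from others: 214 of 5908 eligible genes, or 3.62%, were lost in at least 1 library (127 in 1, 50 in 2 and 37 in 3 or more), among them B3gnt2 with 0.0811 CPM in AX 10 and 153.6 CPM or more elsewhere, Ptprc, the pan-leukocyte gene CD45, with 22.4 CPM in AX 8, Ikbke in AX 6, and Rasa3 in 6 libraries. Sparse sampling of RNA is argued against by the abundance of the lost genes. The share lost among the 25% most abundant genes was 0.907 of that among the 25% least abundant (95% interval 0.621 to 1.33). For amlexanox, 0.0% of lost genes were lost in 4 or 5 libraries of 1 group and none of the other. Genes lost in fewer than 4 libraries, among them the 127 lost in 1 and the 50 lost in 2, could not meet that rule. It therefore argues only against a loss across nearly all of 1 group, and a weaker or uneven effect of amlexanox was not tested. Reads counted for an overlapping gene on the same strand cannot explain the 77.6% of lost genes that have no such annotated partner. That share follows from gene coordinates alone, and overlaps on the opposite strand were not tested. For the other 48 as a set, B3gnt2 and Ptprc among them, this explanation cannot be told apart. Partners were more frequent than among other genes (22.4% against 10.1%, two-sided Fisher exact p = 3.05e-07). They gained at least 0.5 of the lost CPM for 42 of 104 values, while the median gain was 0.0400 (interval 0.000259 to 0.489). Adnp, whose span overlaps that of Gm20716, was lost in NC 4, NC 5, AX 7, AX 9 and AX 10, and Gm20716 in NC 1, NC 2, NC 3, AX 6 and AX 8. In this pair the losses went as reads counted for the other gene would. Lost genes were longer than abundance-matched genes by a ratio of 1.91 in median length (10060 against 5266 bp, permutation p = 2e-05, the smallest the resampling could give). Assignment of reads to isoforms of long genes in the authors' counting is thus a candidate explanation, a hypothesis found and tested on the same data, and the reads were not analysed here. Whether differences in cell mixture account for some lost genes was not tested. The neutrophil granule gene Camp was lost in NC 4, where Ltf of the same list was also lowest, at 13.3 CPM. The neutrophil list as a whole was lowest in AX 10, at 7.41 mean log2 CPM, against 7.86 in NC 4. Ccr2 and Fn1 of the monocyte list were lost in AX 6, the library lowest on that list, at 4.75, and Fn1 also in NC 1 and NC 3. The list levels include these genes.

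AX 6 and NC 1, of different groups, lay apart from the other 8 libraries on the first principal component, with shifts of 2.37, 1.67, 3.36 and 1.92 log2 units in the mesothelial, stromal, gut and red blood cell lists and of -0.25, -0.30, -0.43 and -0.66 in the B cell, T cell, neutrophil and monocyte lists. Both also lay above all other 8 libraries on the inflammatory cytokine, coagulation and handling and heat shock lists (shifts of 1.17, 0.886 and 0.865). Handling or inflammation as a cause of the pair was not tested. An effect of amlexanox shared by the AX libraries is argued against as the source of the pair's shift on this component. On it the other 4 AX libraries lay from the other 4 NC libraries by -0.0115 ± 0.113 (SE) of the shift of AX 6. AX 6 and NC 1 lie farthest out on this axis, so the value says nothing about effects of amlexanox off it. An effect in AX 6 alone was not tested. A lower share of leukocytes cannot be told apart from more cells of the lining and gut, because 5 of 9 leukocyte lists lay lower and 4 higher (median shift -0.127, SD 0.417). More mesothelial and gut tissue cells may account for the pair, and that also stays open, because the lower of the pair exceeded the highest other library by 0.88 log2 on the mesothelial list, short of the 1 set for it, and on the gut list AX 6 at 4.72 lay near NC 4 at 4.33. Msln and Krt18 reached 821 and 539 CPM in AX 6 and 206 and 142 CPM in NC 1, 2 of the 14 tested markers are held by another list, and the labels describe no sort or gate that would remove such cells.

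Fewer genes had an unadjusted p under 0.05 than the 5% chance gives, namely 113, while other splits gave 70 to 2427. As few genes came from 11 of the 100 splits, the real one included (lowest other split 70), so chance placement of the libraries is not excluded. Splits that part AX 6 from NC 1 gave a median of 177 genes and those that keep them together 1149, which fits a spread raised by 2 unlike libraries, 1 in each group. Having the closest library of all 10 in the other group was matched by 3 of 100 splits, the real one included (real value 10, highest other 10). That is under the 5% set beforehand as the limit for chance. AX 6 and NC 1 are each other's closest library, so only splits that part them can reach 10. Among the 57 splits that part them the share is 5.26%. This comparison was not part of the limit set beforehand, and neither share is adjusted for the other split tests, so chance is not excluded. Shared handling of libraries across the groups was not tested, since the labels give no batch.

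The real count of changed genes was 0 in edgeR, with 113 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. Any split gives at least 0, so that all 100 of 100 splits did says nothing about chance, with or without a minimum absolute log2 fold change of 1. Of the splits, 85 gave 0 genes; the highest, 431 (406 with that minimum), set NC 1, NC 3, AX 6, AX 7 and AX 8 against the rest, and the next gave 4. A structure of the samples may lie behind that 1 split, but this was not tested. The 7 gene lists were matched by 78 of 100 splits (median of the others 10, highest other 21), so that chance is not excluded for the number of lists.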

How the results depend on the processing

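The mesothelial covariate, robust fits, leaving out AX 6 and NC 1 together and leaving out lost genes were chosen after seeing the data. No paired analysis was possible because AX and NC libraries share no replicate number. The count of changed genes was 0 in 23 of 24 alternatives, with 79 to 433 genes at an unadjusted p under 0.05; leaving out 1 library gave 0 to 1, the 1 being Rnf24 without NC 3 (log2 fold change -5.75, adjusted p = 0.0174 with edgeR), and the count with an absolute log2 fold change of at least 1 likewise ran from 0 to 1. Rnf24, chosen after its values were seen, is tested there because the filter then asks for fewer libraries; it had 317, 230, 50 and 182 counts in NC 1, NC 2, NC 4 and NC 5, and 2 to 5 in NC 3 and the AX libraries. Il10 had a negative log2 fold change in all 24 alternatives, from -0.62 to -0.02, and passed in none. The count of lists, 7, became 0 with an estimated correlation and 0 with fry, and 11 without AX 6 and NC 1. The estimated correlations of the 7 lists ran from 0.066 (pyruvate entry and citric acid cycle) to 0.85 (mesothelial cells), all above the preset 0.01. Only this setting differed between the camera runs, so the calls of camera rest on the low preset. For fry the cause was not tested. Leaving out 1 library gave 5 lists (without AX 10) to 14 (without NC 5). Of the lists, oxidative phosphorylation passed in each alternative except an estimated correlation and fry (leaving out 1 library: adjusted p 4.29e-09 to 0.000245), and the mesothelial list ran from 0.000186 to 0.85 and changed direction without AX 6. Of the lists that did not pass with all libraries, NF-kappaB targets passed as lower in 8 of 19 alternatives and gut epithelium as lower in 9. Type I interferon passed as higher and oxidative stress as lower in 5 each, and handling and heat shock as higher in 3. IL-10 targets, neutrophils, plasma cells and ribosomal proteins passed as lower, and mast cells as higher, in 2 each. All these calls used the preset correlation. With an estimated correlation and all libraries, these lists gave adjusted p from 0.835 (NF-kappaB targets among others) to 0.951 (ribosomal proteins). With the mesothelial covariate, inflammatory cytokines passed as lower and efferocytosis as higher in AX (adjusted p 0.0373 each, preset correlation). With an estimated correlation and all libraries these 2 lists gave adjusted p = 0.99 and 0.835. Slc16a1 turned from 0.08 to -0.21 with library quality weights, -0.035 on FPKM, -0.14 with the mesothelial covariate and -0.24 without AX 6 and NC 1, and ran from -0.21 to 0.19 leaving out 1 library. Il6 turned from 0.92 to -0.065, -0.32 and -0.13 with the quality weights, with the mesothelial covariate and without AX 6 and NC 1, and ran from -0.72 to 1.51 leaving out 1 library. Il1b ran from -0.17 to 0.12 and Ikbke from -0.37 to 0.12. The cause was not tested for these reversals. The other named genes kept their direction wherever they were tested. Counting depth of 10221170 to 13806885 counts limits genes near 1 CPM such as Ldhb; for abundant genes the spread between libraries sets the limit.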

Other observations

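The splits of single lists and the relations of Il10 were chosen before their values were seen, and the other observations after. Mitochondrial ATP synthase gene mt-Atp6 and its neighbour mt-Co3, which are transcribed together, were at similar levels in AX 6 (14200 and 13771 CPM), AX 10 (21686 and 21380 CPM), NC 4 (13168 and 12520 CPM) and NC 5 (16631 and 16131 CPM), but mt-Atp6 was far lower than mt-Co3 in NC 1 (1081 and 9054 CPM), NC 2 (548 and 5036 CPM), NC 3 (1148 and 9367 CPM), AX 7 (1166 and 8633 CPM), AX 8 (2902 and 25923 CPM) and AX 9 (828 and 6636 CPM). Gapdh, a housekeeping enzyme with many processed pseudogenes in the mouse genome, was listed at only 56.6 ± 31.6 CPM in AX and 55.4 ± 18.8 CPM in NC, and reads shared with copies make this level uncertain. The ferritin light chain gene Ftl1, which also has many copies, stood at 9780 CPM in NC 5, 7051 CPM in NC 2 and 6971 CPM in NC 4 and at 2513 to 3594 CPM in the other libraries.

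The gut genes were unevenly spread. Fabp2, an intestinal fatty acid binding protein gene, stood at 254 CPM in NC 1, 98.1 CPM in NC 4 and 73.9 CPM in AX 6, and at 1.36 to 18.8 CPM in the other libraries. Cxcl1 and Ptgs2, a neutrophil attractant and an inducible cyclooxygenase, followed AX 6 (8088 and 10125 CPM) and NC 1 (2171 and 2947 CPM), against 169.8 to 566.4 CPM and 177.9 to 989.7 CPM elsewhere.

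For nuclear-encoded oxidative phosphorylation, only the real split, 1 of 100, gave a camera p as small as 1.08e-08; the smallest of the other splits was 7.09e-08, but the list was singled out for that p, as the smallest of 40, so this does not exclude chance. The exact permutation p of the mean list level was 0.0714. A p as small for some list came from 49 of 100 splits, the smallest among the others being 5.76e-34, so chance is not excluded for a list of that rank.

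Whether Il10 followed other levels was tested across the 8 libraries other than AX 6 and NC 1, for 3 relations with exact permutation p. As a hypothesis, Il10 may follow glycolytic gene expression, but Pearson's r was 0.193 (p = 0.635, adjusted 0.635) and Spearman's rho -0.262 (p = 0.536, adjusted 0.536), with r = 0.553 without the 2 libraries farthest from the median list level. With the other members of the IL-10 list r was 0.616 (p = 0.0923, adjusted 0.138) and rho 0.405 (p = 0.327, adjusted 0.490), with r = 0.613 without the 2 farthest. With the neutrophil list r was 0.808 (p = 0.0275, adjusted 0.0826) and rho 0.524 (p = 0.197, adjusted 0.490), and r = -0.307 without NC 3 and AX 10, so that relation rests on these libraries. None of the 3 passed, and each group alone has too few libraries for a correlation.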
